A study of Homo sapiens with 12 samples.

How the data were processed

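Total RNA from cultured KYSE450 cells was sequenced in 12 libraries, 6 from control cells and 6 from cells that overexpressed DLGAP1-AS2, and the groups were taken from the labels. The columns of the table name the control libraries by another prefix than the sample titles do, and they were matched to the titles by group and number. Per the file headers, the authors deposited raw counts per gene and FPKM values per gene for each library. The counts are whole numbers without normalization, and the FPKM values were made by the authors from the counts by gene length and library total. The submitters' processing notes name HISAT2, DESeq and the genome build GRCh38. The read counter, the annotation release, the strand setting and the software versions are not given in the sources used here. The table held 58940 genes, of which 58676 carried Ensembl identifiers and 264 carried identifiers outside that set. All 58676 Ensembl identifiers were found in GENCODE release 29, which supplied positions, gene types and overlaps.

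The counts were the basis of every test, and the FPKM values served only to recover gene length. Total counts per library were 30701859 to 52383656 in control and 31835412 to 46700943 in overexpression. Genes with low counts were removed with filterByExpr, which left 16711 genes, 177 of them outside the Ensembl set. Libraries were scaled with TMM, and overexpression was compared with control by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The common biological coefficient of variation was 13.6%. Levels are given as CPM on the TMM scale, as mean ± SD over 6 libraries, and log2 levels per library were computed with a prior count of 2. The target was also compared with an exact two-sided permutation test of its log2 CPM.

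Before the data were examined, 39 gene lists and the rule for named genes were fixed. Lists with at least 5 tested members, 37 in all, were compared with camera of limma 3.58.1 at a preset correlation of 0.01, and p was adjusted over those lists. Camera with an estimated correlation and the rotation test fry were run beside it. Members were also counted after adjustment over the list alone. The rule names DLGAP1-AS2, and the 12 genes with the largest increase and the 12 with the largest decrease among changed genes that have a symbol, a mean of at least 1 CPM in the higher group and no overlap between the groups. It also allows all tested members of the lists of YAP/TAZ targets and phosphatidic acid synthesis, and from each other list up to 4 changed members with the smallest p. Of the members the rule allows, some whose call rested on few of the fits that left out 1 library are given only in the counts. DLGAP1 and DLGAP1-AS1 fall outside the rule and were chosen after their values were seen, for their place at the locus. The gene families and their members named after the report were also chosen then. PTPRC, CORO1A and TYROBP, from the fixed leukocyte list, were named for a test written before its result was seen.

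The alternatives tried were the size factors of DESeq2 in edgeR, library totals as the only scaling, no filter on low counts, a mean of at least 5 CPM, DESeq2 1.42.0 with limma-voom for the gene lists, a block by replicate number, a merge of libraries with neighbouring sample records, a fold change of at least 1.5, and leaving out each library in turn. Chosen after seeing the data were fits without control replicates 5 and 6, on libraries 1 to 4 only, on libraries 5 and 6 only, with a term for libraries 5 and 6, and with the trends of each library with length and GC content removed (lowess span 0.3). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

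The steps were tested on simulated data of the same size with 16502 genes in the test. Of the genes changed in the simulation, 66.7% were recovered at 1.5-fold (44 of 66), 92.3% at 2-fold (60 of 65) and 98.5% at 4-fold (65 of 66). Of 194 calls, 13 (6.7%) were false. Camera with the preset correlation called 1 of the 37 lists, none of which was changed as a list. Single changed genes could fall in these lists. Genes were simulated independently of each other, so this count does not measure false calls for lists whose genes vary together.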

Results

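The transcriptome of KYSE450, an established line from a human esophageal squamous cell carcinoma, was compared between cells that overexpressed DLGAP1-AS2, a long noncoding RNA gene, and control cells. Sequencing covered 12 libraries, 6 per group, all from total RNA of cultured cells, and the labels name no drug. Total counts lay between 30701859 and 52383656 in the control libraries and between 31835412 and 46700943 in the overexpression libraries. Of 58940 genes in the table, 16711 had enough counts to be tested. The correlation of log2 CPM between libraries of the same group was 0.984 to 0.995. The groups separated along the first principal component, which held 33.99% of the variance. Overexpression replicate 3 stood apart along the second component (16.9%), and control replicates 5 and 6 lay nearer to the overexpression libraries than the other 4 controls did. Control replicates 5 and 6 were also the closest pair of the same group, with a chi-square of 4.68 per gene, and overexpression replicates 5 and 6 were the closest pair of theirs (7.28). In 13 of 37 gene lists control replicates 5 and 6 both lay above (10) or both below (3) the other 4 controls, where chance gives 13.3% for a pair named in advance (this pair was chosen after seeing the data, and lists are not independent). Whether libraries 5 and 6 share a culture or a time is not given in the labels. The p-values of fits on libraries 5 and 6 only rest on the spread within these close pairs. No pair of the same group differed by as little as sampling noise, and every library was counted as a replicate. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

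**Figure D1:**
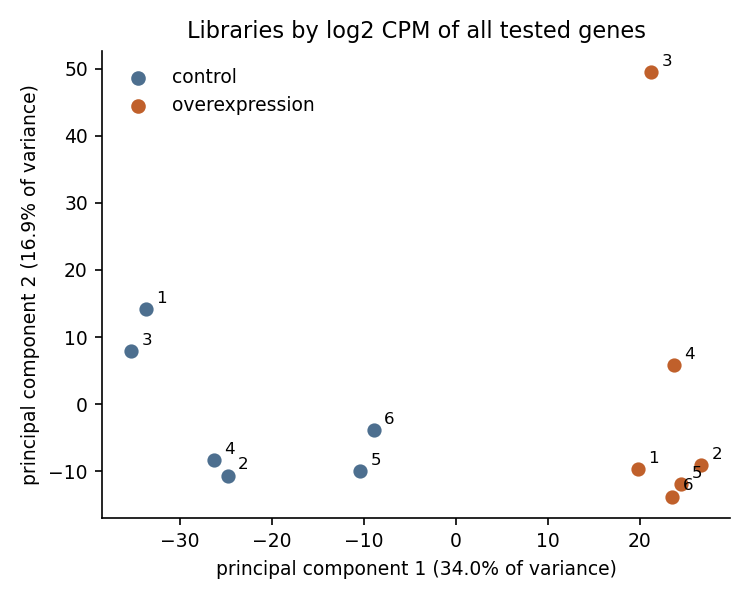
Principal components of log2 CPM over the 16711 tested genes, with the first component on the x axis (33.99% of the variance) and the second on the y axis (16.9%). Each point is a library with its replicate number, in blue for control and orange for overexpression, and overexpression replicate 3 lies alone at 49.5 on the second component.

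DLGAP1-AS2 itself was 9.36-fold higher in the overexpression libraries. Its level was 8.67 ± 1.67 CPM in control and 81.0 ± 7.53 CPM in overexpression (SD, n = 6), and all 6 overexpression libraries, at 68.8 to 90.4 CPM, lay above all 6 control libraries, at 6.74 to 10.8 CPM. The log2 fold change was 3.23 ± 0.12 (SE) with an adjusted p of 3.5e-11 in edgeR's quasi-likelihood test, and an exact two-sided permutation test of log2 CPM gave p = 0.0022, the smallest that 924 arrangements allow. The gene (ENSG00000262001) lies on chromosome 18 from 3603000 to 3608336 on the plus strand of GRCh38. It is annotated as an antisense gene with 2 transcripts inside the span of DLGAP1 (3496032 to 4455335, minus strand), and 0 of its 3 annotated exons overlap an exon of DLGAP1. The counts do not separate transcripts of the introduced copy from those of the gene at its own locus. DLGAP1-AS1, which ends 4648 bases upstream of DLGAP1-AS2 on the same strand, was measured at 4.49 ± 0.865 CPM in control and 5.84 ± 0.522 CPM in overexpression (adjusted p = 0.061). The difference passed the threshold in 3 of the 12 fits that left out 1 library (without control replicate 5 or 6 or overexpression replicate 6, with adjusted p from 0.016 to 0.13 over the 12 fits). It also passed in DESeq2 (adjusted p = 0.018) and in 4 settings chosen after seeing the data. These were the fits without control replicates 5 and 6 (0.0050), on libraries 1 to 4 only (0.010), with a term for libraries 5 and 6 (0.046) and with trends removed (0.032). On libraries 5 and 6 only, also chosen after, the log2 fold change was -0.012 (adjusted p = 0.97). DLGAP1 was measured at 1.63 ± 0.323 and 2.06 ± 0.363 CPM (adjusted p = 0.20). In edgeR, 0 of the 11 tested genes of a list of neighbours on 18p11.31 passed the threshold over all genes, 2 passed higher when adjusted over the list alone, 4 were higher at an unadjusted p under 0.05, and DESeq2 called 2. The set test camera gave that list an adjusted p of 0.11, and 0.49 with an estimated correlation, while the rotation test fry placed it higher (adjusted p = 0.026). Whether the counting used strand is not given in the sources used here, so reads of DLGAP1 and its antisense genes may have been counted together.

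**Figure D2:**
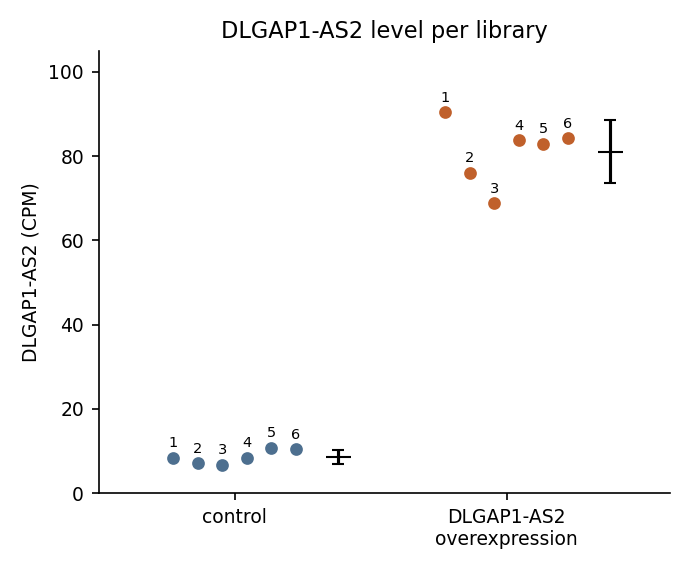
Level of DLGAP1-AS2 in CPM on the y axis for each library, by group on the x axis, with replicate numbers beside the points and the mean ± SD as a bar to the right of each group. The 6 overexpression libraries sit between 68.8 and 90.4 CPM and the 6 control libraries between 6.74 and 10.8 CPM.

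At an adjusted p under 0.05, 1723 genes (10.3% of those tested) differed between the groups, 584 of them higher and 1139 lower in overexpression. Changes of at least 2-fold were counted for 65 higher and 374 lower genes. Among the changed genes, 317 higher and 659 lower had no overlap between the 6 values of each group. For unselected genes, chance gives such a separation for 0.216%. The changed genes were picked by a test of the same values, so their separation is not separate support. Protein-coding genes made up 531 of the higher and 1018 of the lower genes. Both counts moved with 1 library: without overexpression replicate 3, 1078 genes were higher and 1468 lower. Removing each library's trend with gene length and GC content, a setting chosen after seeing the data, gave 1213 higher and 1465 lower genes, so the share of lower genes went from 66.1% to 54.7%.

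Genes of the terminal differentiation of squamous epithelium were among those with the largest decreases. SCGB1A1, which encodes the secretoglobin of airway club cells, was 17.0-fold lower (11.6 ± 5.76 CPM in control, 0.688 ± 0.271 in overexpression), and CYP4B1, a cytochrome P450, was 13.7-fold lower (13.6 ± 7.11 and 1.004 ± 0.171 CPM). Involucrin (IVL), a structural protein of the cornified envelope, was 7.45-fold lower, at 17.6 ± 7.38 CPM in control and 2.37 ± 0.309 CPM in overexpression, with a log2 fold change of -2.90 ± 0.25 (SE) and an adjusted p of 6.4e-07. For SCGB1A1, control replicates 5 and 6 lay nearer to overexpression (6.34 and 5.35 CPM) than the other controls did (9.48 to 20.5 CPM). The same held for IVL (9.60 and 8.59 CPM against 16.6 to 26.9 CPM). The aquaglyceroporin gene AQP3 was 7.30-fold lower (34.6 ± 10.8 and 4.75 ± 0.984 CPM). The remaining genes of the 12 with the largest decreases were the TEAD cofactor VGLL1 (10.3-fold), the epithelial transcription factor ELF5 (9.52-fold), the chloride channel gene CLIC3 (9.14-fold), VILL (8.47-fold), the desmosomal cadherin DSG4 (7.97-fold), GCOM1 (7.55-fold), the calmodulin-like gene CALML5 (7.20-fold) and the keratin KRT23 (6.89-fold). The GCOM1 locus is a read-through of MYZAP and POLR2M, so its reads can be shared with them.

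Most of the 12 largest increases were at low levels. TCIM, a regulator of Wnt signaling, was 10.4-fold higher, from 0.173 ± 0.225 to 1.66 ± 0.107 CPM. The MHC class II genes HLA-DRA (6.50-fold, from 0.512 ± 0.620 to 3.10 ± 0.411 CPM) and HLA-DRB1 (5.27-fold) and the class II invariant chain gene CD74 (4.30-fold, from 1.64 ± 1.66 to 6.79 ± 0.976 CPM) were higher. For these 3 genes together, control replicates 5 and 6 lay closer to overexpression than the other controls did, with a mean log2 difference of 1.05 to overexpression against 3.71 for control replicates 1 to 4. The neurotrophin receptor gene NTRK2 had the highest level of the 12 largest increases, at 33.96 ± 14.5 CPM in control and 120.2 ± 19.2 CPM in overexpression (3.55-fold, log2 fold change 1.83 ± 0.22 SE, adjusted p = 2.3e-05). LONRF2 (4.51-fold), the cell adhesion gene DSCAM (4.03-fold), the microRNA host gene MIR3142HG (3.97-fold), the secretogranin gene SCG2 (3.68-fold), the olfactory receptor gene OR51B5 (3.47-fold) and GPS2 (3.46-fold) were the others among the 12 largest. The call for MIR3142HG, with an adjusted p of 0.041, was kept without control replicate 5 or 6 or overexpression replicate 3 and lost in the other 9 of the 12 fits that left out 1 library (adjusted p 0.014 to 0.082), and in DESeq2 (adjusted p = 0.13). HLA-DRB1 can share reads with other class II genes, and OR51B5, GPS2, MIR3142HG and DSCAM overlap other annotated genes, so their counts are uncertain.

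The list of squamous differentiation genes fell as a group. Of its 23 tested members, 18 were lower and 0 higher over all genes tested in edgeR, 19 were lower when adjusted over the list alone, and 20 were lower and 0 higher at an unadjusted p under 0.05. DESeq2 called 18 lower and 0 higher. The median log2 fold change was -1.14. The set test camera gave an adjusted p of 3.4e-48 with a preset correlation and 0.00089 with an estimated correlation. The small proline-rich proteins SPRR1A and SPRR3, which are cross-linked into the cornified envelope, fell 3.32-fold and 4.42-fold from 338 ± 35.3 and 390.3 ± 60.0 CPM. KRT1, a keratin of suprabasal cells, fell 5.34-fold (26.4 ± 6.11 to 4.93 ± 1.34 CPM), and suprabasin (SBSN) fell 6.74-fold from 2.43 ± 0.667 CPM. The paralogous SPRR genes can share reads. Of 19 tested squamous basal genes, 1 was higher (0 with library totals as the scaling) and 2 lower (3 and 2 when adjusted over the list alone). The lower genes were TRIM29 (1.38-fold) and the keratin KRT15 (1.41-fold, 1152 ± 107 to 816 ± 128 CPM). For the basal list camera gave adjusted p = 0.78, with 0.88 for an estimated correlation.

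**Figure D3:**
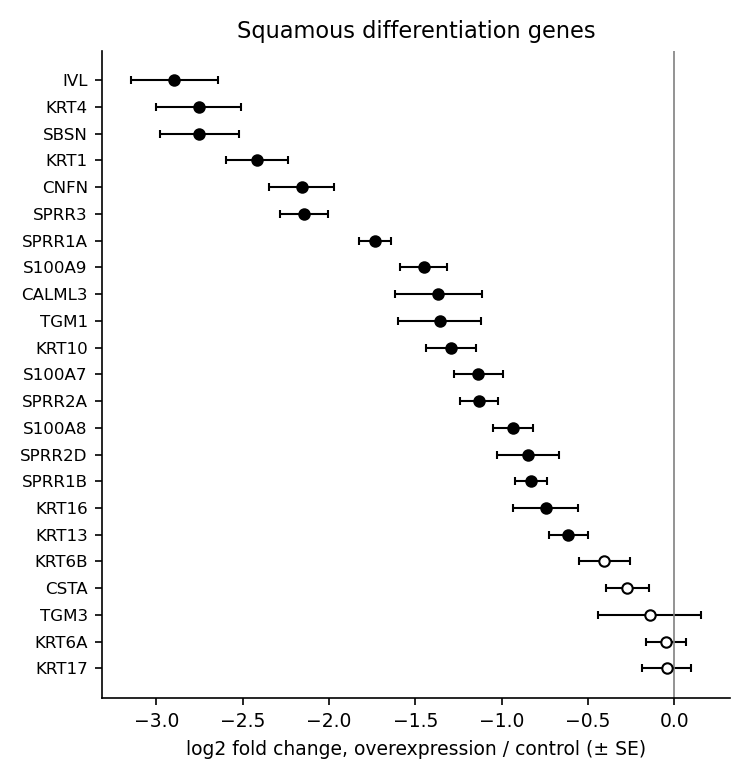
Log2 fold change of overexpression over control on the x axis, with its SE, for the 23 tested squamous differentiation genes on the y axis. Filled points are the 18 genes with an adjusted p under 0.05, all of them lower, with IVL at -2.90.

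Other epithelial groups were also lower. Of 20 tested genes of epithelial junctions, 8 were lower and 1 higher over all genes tested, and 14 and 1 when adjusted over the list alone. The tight-junction genes TJP3 (3.97-fold, 7.34 ± 0.737 to 1.86 ± 0.471 CPM), CLDN4 (3.95-fold, 64.7 ± 26.3 to 16.4 ± 2.85 CPM) and CLDN7 (1.58-fold) fell, as did JUP, which encodes plakoglobin (1.36-fold, 844 ± 88.4 to 619.6 ± 35.1 CPM). Camera placed the list lower with an adjusted p of 1.6e-07, and with an adjusted p = 0.066 for an estimated correlation. By fry the list was lower (adjusted p = 0.00036). Of 8 tested markers of simple epithelium, 5 were lower and 0 higher (6 and 1 when adjusted over the list alone or at an unadjusted p under 0.05, and 5 and 0 in DESeq2). The lower genes included the keratin KRT20 (6.75-fold, 8.07 ± 3.15 to 1.20 ± 0.295 CPM), the mucin MUC1 (2.61-fold), the disulfide isomerase gene AGR2 (1.74-fold) and the transcription factor GATA6 (1.56-fold). For this list camera gave adjusted p = 2.7e-06, and adjusted p = 0.066 with an estimated correlation, and fry placed it lower (adjusted p = 0.00027). Of 16 tested genes of the epithelial-mesenchymal transition, 2 were higher and 1 lower (4 and 2 over the list alone). The gelatinase MMP2 was 1.69-fold higher and the membrane metalloproteinase MMP14 1.37-fold lower (adjusted p = 0.29 for the list, 0.67 with an estimated correlation).

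The series title names YAP signaling, and the list of YAP/TAZ targets did not pass the set test. Of its 22 tested genes, 3 were lower and 0 higher over all genes tested in edgeR, with the same counts when adjusted over the list alone. At an unadjusted p under 0.05, 8 were lower and 1 higher, and DESeq2 called 4 lower and 0 higher. The lower genes were GADD45B (1.66-fold, 5.15 ± 1.598 to 3.12 ± 0.482 CPM), the angiomotin family gene AMOTL2 (1.34-fold, 40.4 ± 7.24 to 30.0 ± 4.34 CPM) and IGFBP3 (1.28-fold, 417 ± 62.1 to 325 ± 49.2 CPM). The call for GADD45B was lost with neighbouring records merged (adjusted p = 0.090) and on libraries 5 and 6 only (0.28). The call for AMOTL2 was lost without control replicate 1, 2 or 5 or overexpression replicate 2 (adjusted p up to 0.083). That for IGFBP3 was lost in 9 of the 12 fits that left out 1 library, all but those without control replicate 2 or overexpression replicate 1 or 3 (adjusted p up to 0.11), and with DESeq2 size factors (0.052). CYR61 (CCN1) was measured at 27.3 ± 10.99 CPM in control and 22.0 ± 4.35 CPM in overexpression (log2 fold change -0.32 ± 0.22 SE, adjusted p = 0.43). CTGF (CCN2) was measured at 1.93 ± 0.864 and 2.14 ± 0.445 CPM (0.15 ± 0.26 SE, adjusted p = 0.79; its sign turned without control replicate 4, at -0.01). ANKRD1 was measured at 0.339 ± 0.138 and 0.396 ± 0.0953 CPM. Camera gave adjusted p = 0.23, and 0.67 with an estimated correlation, with a median log2 fold change of -0.08. Among 24 tested components of the Hippo pathway, 1 was higher and 3 lower (3 and 4 over the list alone), including TEAD2 (1.48-fold higher) and TEAD3 (1.32-fold lower), and camera gave adjusted p = 0.73, with 0.88 for an estimated correlation. The call for TEAD2 was lost without control replicate 1, 2 or 5 or overexpression replicate 1 or 4 (adjusted p up to 0.064), and that for TEAD3 without control replicate 1 or 3 or overexpression replicate 5 or 6 (adjusted p up to 0.053). RNA levels do not measure the activity or location of YAP protein.

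Genes of phosphatidic acid synthesis, also named in the title, went both ways. Of 19 tested genes, 2 were higher and 2 lower (3 and 2 over the list alone). The glycerol-3-phosphate acyltransferase gene GPAT3 was 1.52-fold higher (27.7 ± 8.18 to 41.9 ± 8.79 CPM) and the phospholipase D family gene PLD6 1.41-fold higher (6.93 ± 0.706 to 9.78 ± 2.11 CPM). The phospholipase D gene PLD1 was 1.41-fold lower (14.7 ± 3.65 to 10.4 ± 1.25 CPM) and the diacylglycerol kinase gene DGKA 1.26-fold lower (77.0 ± 8.62 to 61.0 ± 5.18 CPM). The call for GPAT3 was lost without control replicate 1, 3, 4 or 6 or overexpression replicate 2, 5 or 6 (adjusted p up to 0.094), that for PLD6 without control replicate 1 or 3 or overexpression replicate 4 (up to 0.056). That for PLD1 was lost without control replicate 1, 3 or 4 or overexpression replicate 1, 2 or 4 (up to 0.089). The PLD1 call was also lost with neighbouring records merged (0.092) and with the block by replicate number (0.087). On libraries 5 and 6 only, in a fit chosen after seeing the data, its log2 fold change was 0.018 (adjusted p = 0.93). GPAM, the mitochondrial acyltransferase gene, was measured at 27.0 ± 3.39 and 30.6 ± 5.54 CPM (adjusted p = 0.41). Camera gave adjusted p = 0.23 for the list, and 0.59 with an estimated correlation. A list of phosphatidic acid use also held related lipid steps, such as cardiolipin synthesis, that do not act on phosphatidic acid itself. Of its 15 tested genes, 3 were higher and 0 lower in edgeR (4 and 0 over the list alone, at an unadjusted p under 0.05 and in DESeq2). These were the phosphatidate phosphatases LPIN1 (1.43-fold, 9.10 ± 0.830 to 12.9 ± 1.96 CPM) and PLPP1 (1.66-fold, 15.3 ± 4.03 to 25.4 ± 3.44 CPM) and the cardiolipin synthase CRLS1 (1.24-fold). The rotation test fry, which asks whether a list's genes move on balance one way, gave adjusted p = 0.0013 for this list, and camera 0.078, or 0.33 with an estimated correlation and 0.0054 without the low-count filter. In fatty acid synthesis and desaturation, 2 of 19 tested genes were higher, the desaturase FADS1 (1.38-fold) and ATP citrate lyase ACLY (1.19-fold). In that list 0 were lower in edgeR, DESeq2 called 3 higher and 0 lower, and 6 were higher and 2 lower at an unadjusted p under 0.05 (3 higher and 0 lower over the list alone; camera adjusted p = 0.20, 0.67 with an estimated correlation). In cholesterol synthesis, 1 of 25 tested genes was lower in edgeR, also when adjusted over the list alone, 2 in DESeq2 and 3 at an unadjusted p under 0.05. In that list 0 were higher in edgeR, DESeq2 or at an unadjusted p under 0.05 (camera adjusted p = 0.73, 0.88 with an estimated correlation).

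For resistance to chemotherapy, the third subject of the title, lists of drug transport, DNA repair, p53 targets, the BCL2 family and NRF2 targets were tested, and camera passed none of them in the main fit. Of 15 tested genes of drug efflux and platinum transport, 2 were higher and 1 lower (2 and 4 over the list alone), the lower gene being the efflux pump ABCC5 (1.27-fold, 132 ± 12.1 to 103 ± 9.68 CPM). The higher genes were the transporter gene ABCC4 (1.23-fold, 44.0 ± 2.94 to 54.0 ± 6.27 CPM, adjusted p = 0.027) and LRRC8D (1.20-fold, adjusted p = 0.041). Both are left out of the named genes that were followed over other settings below. With library totals as the only scaling, 0 of these genes were higher and 2 lower. Of 29 DNA repair genes, PARP1 was 1.15-fold higher (236 ± 15.7 to 272 ± 11.5 CPM), a call lost without control replicate 1, 2, 3 or 4 or overexpression replicate 1, 4 or 5 (adjusted p up to 0.078) and with library totals as the scaling (0.072). DESeq2 called 5 DNA repair genes higher and 7 were higher at an unadjusted p under 0.05, while 0 were lower in edgeR, DESeq2 or at an unadjusted p under 0.05, and 0 passed over the list alone. Of 25 p53 targets, 4 were lower and 0 higher in edgeR and 5 and 0 over the list alone and in DESeq2, with 6 lower and 5 higher at an unadjusted p under 0.05. The cell-cycle inhibitor CDKN1A fell 1.78-fold (27.1 ± 2.30 to 15.2 ± 1.56 CPM, adjusted p = 3.6e-06), the stress sensor SESN2 1.96-fold and TP53INP1 2.01-fold. The call for TP53INP1 was lost on libraries 5 and 6 only, a fit chosen after seeing the data (log2 fold change -0.34, adjusted p = 0.19). Of 15 BCL2 family genes, the pro-apoptotic BCL2L11 was lower (1.29-fold, 15.4 ± 0.843 to 11.9 ± 1.03 CPM) and 0 were higher in edgeR, DESeq2 or at an unadjusted p under 0.05 (2 lower and 0 higher over the list alone, 2 lower in DESeq2, 4 lower at an unadjusted p under 0.05). Of 25 NRF2 targets, 5 were lower and 0 higher in edgeR, also over the list alone, while DESeq2 called 5 lower and 1 higher, and 6 were lower and 2 higher at an unadjusted p under 0.05. The aldo-keto reductase AKR1B10 fell 2.73-fold (17.6 ± 4.88 to 6.49 ± 1.63 CPM) and the glutamate-cysteine ligase subunits GCLM and GCLC 1.47-fold and 1.302-fold. Camera's adjusted p was 0.29 for drug transport, 0.10 for DNA repair, 0.24 for p53 targets, 0.29 for the BCL2 family and 0.39 for NRF2 targets, and with an estimated correlation 0.67, 0.59, 0.59, 0.59 and 0.74. DNA repair passed camera, higher, without overexpression replicate 3 (adjusted p = 0.015), without the low-count filter (0.022) and on libraries 5 and 6 only (0.0050), where NRF2 targets also passed, lower (0.0073). The rotation test fry placed p53 targets (adjusted p = 0.0030) and the BCL2 family (0.019) lower.

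Of the growth-related lists, those of MYC activity, S phase entry and mitosis passed camera with the preset correlation and not with an estimated one. By the rotation test fry, MYC activity (adjusted p = 0.0067) and S phase entry (0.0055) were higher, and mitosis did not pass (0.20). Of 25 genes of MYC activity and ribosome biogenesis, 6 were higher and 0 lower in edgeR (12 and 0 over the list alone, 10 and 0 in DESeq2, 13 and 0 at an unadjusted p under 0.05), with a median log2 fold change of 0.19. Nucleolin (NCL) was 1.15-fold higher (2056 ± 54.2 to 2372 ± 66.5 CPM). With library totals as the scaling, 2 of these genes were higher. Camera gave the list adjusted p = 1.5e-05, and 0.34 with an estimated correlation. For S phase entry, 1 of 25 genes was higher, the replicative helicase gene MCM2 (1.21-fold). DESeq2 called 5 higher and 0 lower, and 7 were higher and 1 lower at an unadjusted p under 0.05 (1 and 0 over the list alone and 0 lower in edgeR; camera adjusted p = 0.013, 0.43 with an estimated correlation). For mitosis, 0 of 26 genes passed in edgeR over all genes or over the list alone, or in DESeq2, and 5 were higher at an unadjusted p under 0.05. The list's camera call (adjusted p = 0.0091) was lost with an estimated correlation (adjusted p = 0.67) and without control replicate 2 (0.069) or 5 (0.058). Of 14 replication histone genes, 4 were lower and 0 higher in edgeR (6 and 0 over the list alone, 5 and 0 in DESeq2, 7 and 0 at an unadjusted p under 0.05). The decreases included HIST1H2AC 1.79-fold and the linker histone HIST1H1C 1.499-fold (adjusted p = 0.10 for the list, 0.67 with an estimated correlation). The list passed, lower, without the low-count filter (0.024), with a mean of at least 5 CPM (0.019) and without control replicate 2 (0.042). Whether poly(A) RNA was selected is not given in the sources used here, and most histone transcripts lack a poly(A) tail. Of 26 genes of histone methylation and histone chaperones, 3 were higher, including the demethylase KDM1A (1.15-fold), and 0 lower in edgeR. There were 3 higher and 1 lower in DESeq2 and over the list alone, and 6 higher and 3 lower at an unadjusted p under 0.05 (adjusted p = 0.29, 0.59 with an estimated correlation). In edgeR and DESeq2, 0 of 31 cytosolic ribosomal protein genes, 0 of 26 nuclear genes of oxidative phosphorylation and 0 of 13 mitochondrial genome transcripts passed, also over each list alone, with 2, 0 and 0 higher at an unadjusted p under 0.05. Camera gave adjusted p = 0.17, 0.36 and 0.24, and 0.81, 0.86 and 0.74 with an estimated correlation. Ribosomal protein genes passed camera, higher, without overexpression replicate 1 (0.034) and without the low-count filter (0.028). In overexpression replicate 3 alone, ribosomal protein genes stood 0.52 and oxidative phosphorylation genes 0.40 above the control mean on the log2 scale. Of 15 snoRNA host genes, 0 passed in edgeR over all genes or over the list alone, DESeq2 called 1, and 2 were higher and 1 lower at an unadjusted p under 0.05 (adjusted p = 0.24, 0.69 with an estimated correlation).

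Members of several stress and signaling lists changed, in most of these lists in both directions. In the ATF4 amino acid response, 6 of 25 tested genes were lower and 3 higher (7 and 3 over the list alone). The cytokine GDF15 fell 4.48-fold (9.59 ± 2.55 to 2.15 ± 0.558 CPM), the glutathione-degrading enzyme CHAC1 2.59-fold and the pseudokinase TRIB3 1.47-fold (adjusted p = 0.13, 0.65 with an estimated correlation). In the unfolded protein response, 2 of 20 were higher and 1 lower (6 and 2 over the list alone), with the chaperone HYOU1 1.16-fold higher and the transcription factor XBP1 1.34-fold lower (adjusted p = 0.23, 0.59 with an estimated correlation). Of 18 heat shock genes, 3 were higher, including the mitochondrial chaperonin HSPD1 (1.22-fold, 1944 ± 64.5 to 2374 ± 181 CPM), and 0 lower in edgeR (4 and 0 in DESeq2, 5 and 1 over the list alone, and 7 and 1 at an unadjusted p under 0.05). Camera's adjusted p of 0.038 rose to 0.67 with an estimated correlation. That call was also lost without control replicate 3, 4, 5 or 6 or overexpression replicate 2 or 3 (adjusted p up to 0.13). Of 29 genes of hypoxia and glycolysis, 5 were higher and 2 lower (10 and 3 over the list alone). Lactate dehydrogenase LDHA was 1.20-fold (2018 ± 97.5 to 2421 ± 121 CPM) and PFKFB4 1.57-fold higher, and the lactate transporter SLC16A3 2.24-fold and VEGFA 1.45-fold lower. Camera's adjusted p was 0.037, and 0.65 with an estimated correlation. The list's call was lost without control replicate 2, 3 or 4 or overexpression replicate 3 or 5 (adjusted p up to 0.093). Its mean log2 level was 0.12 and 0.14 in control replicates 5 and 6 and -0.19 to 0.04 in the other controls. In fits chosen after seeing the data, the call was lost on libraries 5 and 6 only (adjusted p = 0.39) and kept without control replicates 5 and 6 (0.014), with 10 genes higher and 2 lower. Of 27 immediate early genes, 8 were lower and 0 higher in edgeR and DESeq2, also over the list alone, with 10 lower and 3 higher at an unadjusted p under 0.05. NR4A2 fell 1.75-fold, the mRNA decay factor ZFP36 1.66-fold and JUNB 1.41-fold (adjusted p = 0.055, 0.67 with an estimated correlation). The list passed camera, lower, without control replicate 3 or 4 or overexpression replicate 2, 5 or 6 (adjusted p 0.0013 to 0.047), without the low-count filter (0.0039) and with a mean of at least 5 CPM (0.019). It also passed camera, lower, with the block by replicate number (0.012). Of 20 TGF-beta targets, 5 were lower and 2 higher, also over the list alone. The inhibitors CDKN2B and ID1 fell 1.62-fold and 1.49-fold, and the collagen IV genes COL4A1 and COL4A2 rose 1.52-fold and 1.42-fold (adjusted p = 0.29, 0.67 with an estimated correlation).

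Members of the interferon list changed in both directions, and of the inflammatory list 0 passed in edgeR. Of 23 tested genes of the interferon response, 4 were lower and 2 higher (5 and 2 over the list alone). The RNA-sensing enzyme OAS1 fell 3.72-fold (17.9 ± 3.52 to 4.80 ± 1.28 CPM) and the antiviral GTPase MX2 4.03-fold (3.41 ± 0.959 to 0.834 ± 0.247 CPM). The RNA sensor IFIH1 rose 1.73-fold (4.84 ± 1.23 to 8.37 ± 0.899 CPM). For this list camera gave adjusted p = 0.15, and 0.67 with an estimated correlation. The list passed, lower, without control replicate 2 (adjusted p = 0.015), without the low-count filter (0.028) and on libraries 5 and 6 only (4.1e-08). It also passed, lower, with the block by replicate number (0.033). Its mean log2 level was 0.54 and 0.47 in control replicates 5 and 6, above the -0.62 to -0.12 of the other controls, and without these 2, in a fit chosen after seeing the data, 4 genes were higher and 3 lower. Of 14 antigen presentation genes, 1 was higher, the peptide transporter TAP2 (1.31-fold), and 1 lower, also over the list alone (adjusted p = 0.18, 0.67 with an estimated correlation). Control replicates 5 and 6 lay at 0.29 and 0.31 for this list, the other controls at -0.20 to -0.09, and without these 2 in the same fit 5 genes were higher and 0 lower and camera's adjusted p was 0.0020. The list was also higher on libraries 1 to 4 only (0.00046) and without the low-count filter (0.043), and lower on libraries 5 and 6 only (adjusted p = 0.0070). Of 18 NF-kB and inflammatory cytokine genes, 0 passed over all genes in edgeR or over the list alone, DESeq2 called 1 higher, and 2 were higher at an unadjusted p under 0.05. Camera's adjusted p of 0.019 for this list became 0.67 with an estimated correlation, 0.091 without control replicate 1, 0.11 without control replicate 3 and 0.051 with a mean of at least 5 CPM. Its mean log2 level ranged from -1.48 to 1.20 among the control libraries around their own mean, and from 0.34 to 0.76 among the overexpression libraries, with control replicates 5 and 6 above all 6 of them. Without those 2 controls 12 of the 18 genes were higher and 0 lower in edgeR, and on libraries 5 and 6 only the list turned lower (adjusted p = 9.9e-09), both in fits chosen after seeing the data.

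Markers of other cell types were few and low. Of 12 leukocyte markers, 1 was tested, and it did not pass over all genes, over the list alone, at an unadjusted p under 0.05 or in DESeq2. Of 10 endothelial markers, 2 were tested, and VWF was 3.17-fold lower (3.72 ± 1.52 to 1.17 ± 0.269 CPM); 1 was also higher over the list alone, at an unadjusted p under 0.05 and in DESeq2. Of 12 fibroblast markers, 6 were tested, and 2 were higher and 0 lower in edgeR and DESeq2 (3 and 0 over the list alone, 3 and 1 at an unadjusted p under 0.05). They were THY1 (2.65-fold, 0.243 ± 0.126 to 0.641 ± 0.185 CPM) and the proteoglycan gene LUM (2.08-fold, 0.786 ± 0.422 to 1.599 ± 0.284 CPM). The call for LUM was lost without control replicate 3, overexpression replicate 4 or overexpression replicate 6 (adjusted p up to 0.052). Camera gave the fibroblast list adjusted p = 0.13, and 0.44 with an estimated correlation, while fry placed it higher (adjusted p = 0.021). Of 12 markers of neurons and of embryonic kidney lines, 6 were tested, and NEFL was 1.501-fold lower with 0 higher in edgeR and DESeq2, also over the list alone, and 1 higher at an unadjusted p under 0.05 (adjusted p = 0.71, 0.81 with an estimated correlation). The lists of leukocyte and endothelial markers had too few tested genes for camera.

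**Figure D4:**
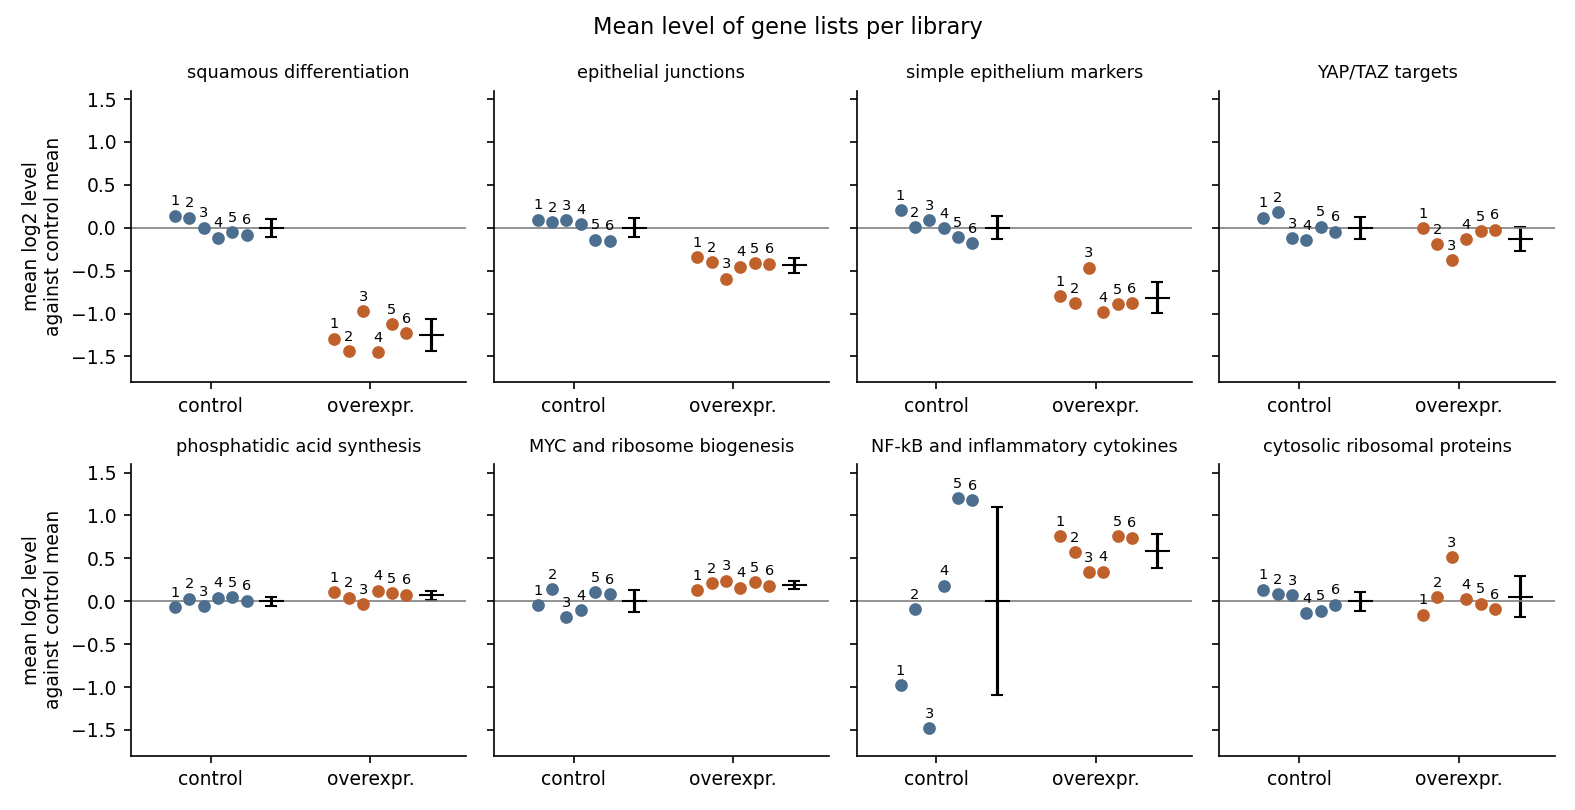
Mean log2 level of 8 gene lists per library against the mean of the control libraries (y axis), for control (blue) and overexpression (orange) on the x axis, with replicate numbers and the mean ± SD as bars. The squamous differentiation list separates the groups, the NF-kB list spreads from -1.48 to 1.20 among the controls, and the cytosolic ribosomal protein list has overexpression replicate 3 at 0.52.

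Across the 37 lists with at least 5 tested members, 9 passed camera with the preset correlation, 6 higher and 3 lower, and 1 passed with an estimated correlation, that of squamous differentiation. The rotation test fry passed 10 lists, 5 of which camera did not pass with the preset correlation. It did not pass 4 of camera's 9, those of mitosis, NF-kB, hypoxia and glycolysis, and heat shock.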

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

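The tests of unusual libraries, of the spread of the NF-kB list among controls, of carry-over, of a wrong label, of loss of a region as the whole cause and of the depth of overexpression replicate 3 were chosen after the results were seen. The genes lower as a group in squamous differentiation had a median log2 fold change of -1.14. That median was -1.14 with each library's trends with length and GC content removed, which argues against such trends as the whole cause. With every library thinned to the smallest total it was -1.13. Random thinning keeps the expected ratios between libraries, so this value cannot decide on sequencing depth. The totals of the groups overlapped (30.7 to 52.4 M in control, 31.8 to 46.7 M in overexpression), so depth did not divide the groups. All 6 overexpression libraries lay below all 6 control libraries, and the highest median over the 12 fits that left out 1 library was -1.09, which argues against a few unusual libraries. An effect of DLGAP1-AS2 on differentiation and a difference between the cultures in density or clonal origin stay open, since the labels do not separate them. Loss of a region of chromosome 1 is argued against as the whole cause of the lower members there, since the other genes of the region lay 0.74 ± 0.17 (SE) above the family genes on the log2 scale (KRT1 and SBSN lie on other chromosomes).

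HLA-DRA, HLA-DRB1 and CD74 were higher in overexpression, as was the NF-kB list by camera with the preset correlation only (0 of its genes passed in edgeR), and for both 4 of the 6 controls were low while control replicates 5 and 6 were not. For the NF-kB list, variation among controls that the groups do not explain is a candidate explanation: 2 controls lay above and 4 below all overexpression libraries, and the list's p with an estimated correlation was 0.44. For HLA-DRA, HLA-DRB1 and CD74, the mean log2 difference to control replicates 5 and 6 was 1.05 ± 0.20 (SE), against 3.71 to control replicates 1 to 4, and with only 2 such controls an effect of the groups and variation among controls cannot be told apart. Carry-over of overexpression material into control replicates 5 and 6 is argued against, since the class II genes would need shares of 40.0% (HLA-DRA), 42.2% (HLA-DRB1) and 51.3% (CD74) and DLGAP1-AS2 one of 4.01%, at least 9.98 times less. Leukocytes stay open: PTPRC, CORO1A and TYROBP together were -0.21 CPM from control to overexpression, but PTPRC went from 0.253 to 0.0873 CPM, CORO1A from 0.669 to 0.620 and TYROBP was at 0, so the bound written before the test was wrong for markers this near the floor.

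Overexpression replicate 3 had a mean correlation of 0.985 with its group, set below the others by more than Dixon's critical value allows. Recovery of RNA that depends on length or on GC content is consistent with its values: across genes, its deviation from the other 5 libraries had a Spearman's rho of -0.36 with length and 0.49 with GC content, the largest in size of the 6 (genes are not independent replicates). Control replicate 4 had a rho of -0.47 with GC content and yet the highest mean correlation of the controls (0.991). A GC trend of about this size therefore need not set a library apart. Removing the trends brought the mean correlation of overexpression replicate 3 to 0.989, still the lowest of its group, so they account for part of the distance. A control library under a wrong label is argued against by its DLGAP1-AS2 level of 68.8 CPM, above all controls, and the lowest depth by its total of 33.9 M counts, above that of overexpression replicate 2. No biological explanation was tested, since the design gives none for 1 library.

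Of 276 groups of 6 values examined, 19 (6.88%) had a highest or lowest library set apart beyond Dixon's critical value, where chance gives about 1 in 20. Overexpression replicate 3 held 10 of the 19. In that library the levels were 38.1 CPM for CLDN7 and 168 CPM for TRIM29, the highest of the group. Its mean log2 levels against the control mean were the highest of the group for antigen presentation (0.35), cytosolic ribosomal proteins (0.52), nuclear oxidative phosphorylation (0.40) and simple epithelium markers (-0.47). They were the lowest for Hippo pathway components (-0.34), DNA repair (-0.11) and histone methylation and chaperones (-0.12). In overexpression replicate 2, CLIC3 (0.319 CPM) and HIST1H2AC (12.4 CPM) were the highest, and SLC16A3 (1.15 CPM) and the p53 target list (-0.18) the lowest. CYP4B1 was lowest in overexpression replicate 6 (0.681 CPM). Among controls, GCLC was highest in replicate 4 (224 CPM), LDHA (2209 CPM) and HIST1H1C (9.18 CPM) were highest in replicate 1, and NEFL was lowest in replicate 2 (3.31 CPM).

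Other splits of the 12 libraries into 6 and 6 were compared with the real one, 100 in all. As many higher genes as the real 584 came from 1 split, the real one, and as many lower genes as the real 1139 also from 1 split, with 368 genes as the highest other. That highest split differed from the real one by exchanging control replicate 5 and overexpression replicate 3, and it gave 208 genes in one direction and 368 in the other. For both counts this argues against a chance division of these 12 libraries. The splits treat the libraries as exchangeable, and the labels do not say that replicates came from separate cultures. A chance difference between cultures is therefore not excluded. For YAP/TAZ targets, 46 splits gave as small an adjusted p as 0.23, and the smallest other was 9.2e-07, so chance cannot be excluded. For phosphatidic acid synthesis, 22 splits did, with 0.054 as the smallest other, so chance cannot be excluded. As many lists as the real 9 passed in 59 splits, with 19 as the highest other, so chance cannot be excluded for the number of lists (the cause was not tested).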

How the results depend on the processing

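The fits without control replicates 5 and 6, on libraries 1 to 4 or 5 and 6 only, with a term for libraries 5 and 6, and with trends removed were chosen after seeing the data. DLGAP1-AS2 stayed higher and past the threshold in every setting run, and the YAP/TAZ and phosphatidic acid synthesis lists stayed short of it. The main counts were 584 higher and 1139 lower genes and 9 lists. A mean of at least 5 CPM, which tests fewer genes, gave 355 higher and 721 lower, and a 1.5-fold minimum 169 and 706. Higher genes were 944 with DESeq2 (the cause was not tested). They were 201 with neighbouring records merged and 373 on libraries 1 to 4 only, both with fewer samples. On libraries 5 and 6 only, 2088 were higher and 1924 lower and 14 lists passed, although fewer samples were used (the cause was not tested). These libraries were the closest pair of each group (chi-square of 4.68 and 7.28 per gene). The p-values of that fit measure only the spread within such close pairs. With trends removed, 1213 genes were higher and 1465 lower, including 571 of the 584 and 1110 of the 1139. Without the low-count filter 18 lists passed (more genes were tested). Leaving out 1 library gave 400 (without overexpression replicate 5) to 1078 (without overexpression replicate 3) higher genes and 924 to 1468 lower.

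On libraries 5 and 6 only, the NF-kB list turned lower (adjusted p = 9.9e-09), and log2 fold changes turned for CYR61 (0.033), PLD1 (0.018) and DLGAP1-AS1 (-0.012); the cause was not tested. That of CTGF ranged from -0.0060 (without control replicate 4) to 0.34 (without control replicate 1). With neighbouring records merged, which leaves fewer samples, 21 named genes and the heat shock list (adjusted p = 0.058) lost their calls. These were GADD45B (0.090), AMOTL2 (0.11), TEAD2 (0.060), TEAD3 (0.082), PLD1 (0.092), DGKA (0.078), CRLS1 (0.079), ACLY (0.072), ABCC5 (0.074), PARP1 (0.22), BCL2L11 (0.085), MCM2 (0.11), LDHA (0.082), HYOU1 (0.18), HSPD1 (0.058), MMP14 (0.063), NCL (0.16), KDM1A (0.22), LUM (0.080), TAP2 (0.057) and MIR3142HG (0.095). Without the low-count filter, HYOU1 (0.060), NCL (0.061), KDM1A (0.083) and PARP1 (0.086) lost theirs, and GPAT3 did with library totals (0.053) and a mean of at least 5 CPM (0.059). Without that filter the ATF4 (0.029, lower) and fibroblast (0.038, higher) lists passed. The heat shock call was also lost with a term for libraries 5 and 6 (0.057) and with trends removed (0.067). On libraries 5 and 6 only, 11 named genes and the S phase (0.052) and hypoxia lists lost their calls, and fatty acid synthesis (0.0077, higher), TGF-beta targets (0.014, lower) and immediate early genes (0.0077, lower) were among 7 lists that gained one. On libraries 1 to 4 only, 16 named genes and 2 lists lost theirs, and without control replicates 5 and 6, 4 named genes and 2 lists, those of mitosis (0.17) and heat shock (0.14). Over the named genes and all settings, 2188 values kept direction and side of the threshold, 119 lost the threshold, 9 gained it and 4 turned. At the lowest total, 30701859 counts, genes under 1 CPM had the least precise values.

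The values do not settle whether replicate numbers pair the libraries. The correlations of deviations between libraries of the same number were -0.01, 0.22, 0.12, 0.18, 0.12 and 0.07, 4 of 6 over 0.1. Of the 6, 2 were highest with their own number. The labels name no batch shared by libraries of the same number, and the main fit was unpaired. The block by number gave 597 higher and 1151 lower genes, including 477 of the 584 higher and 1036 of the 1139 lower genes of the main fit. It passed 11 lists by camera in place of 9, with interferon response (adjusted p = 0.033) and immediate early genes (0.012) added, both lower. It ended the call for PLD1 (adjusted p = 0.087) and changed no other call of the named genes or, by camera, of the lists.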

Other observations

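The families here were formed by gene symbol after the data were seen, as was the share of changed genes in shifted windows, and 13 families with at least 5 tested genes were compared by camera with an estimated correlation. Mucins had 5 of 6 tested genes lower and 0 higher in edgeR (median log2 fold change -1.86, adjusted p = 5.5e-05), with MUC4 going from 65.8 to 19.4 CPM and MUC16, the cell-surface mucin known as CA125, from 21.9 to 5.61 CPM. Serpins of clade B had 9 of 12 lower (adjusted p = 0.0016), with SERPINB3 going from 15.4 to 4.47 CPM. Keratins had 16 of 32 lower (adjusted p = 0.0057), with the esophageal keratin KRT4 going from 2531 to 375 CPM and KRT13 from 5397 to 3528 CPM. S100 proteins had 8 of 16 lower (adjusted p = 0.026), with S100A9 going from 734 to 268 CPM, and claudins 5 lower and 1 higher of 10 (adjusted p = 0.012). Several of these genes also stand in the fixed lists of squamous differentiation, epithelial junctions and simple epithelium, so the families are not independent of them. MHC class II genes, a family formed after 2 of its genes were seen among the largest increases, had 4 of 5 higher (adjusted p = 0.049). For those 2 and CD74, overexpression lay a mean log2 difference of 1.05 above control replicates 5 and 6 and 3.71 above the other controls. The other 7 families did not pass, among them zinc finger proteins with 20 higher and 5 lower of 406 (adjusted p = 0.46).

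A copy-number difference between the cell populations was tested as a hypothesis along the chromosomes, in 1548 overlapping windows of 50 neighbouring tested genes. By the bound written first, a window median over 0.3 in size, the test was met: the largest median was -0.46, and 4 windows lay over 0.2 and 3 over 0.3. All 4 lay on chromosome 1 between 150982017 and 153977743, a region that holds the epidermal differentiation complex. A second test, chosen after that, counted changed genes inside such windows: 1.39% of the 1723, which argues against copy number as the source of most changes. Within the region, 32 genes of families of the complex had a median log2 fold change of -0.84, with 19 lower. The other 48 genes had a median of -0.10 with an SE of 0.053, 5 lower and 0 higher in edgeR. That value was not far enough from the bound of -0.2 to exclude it, so a loss that shifts the whole region slightly stays open. The medians differed by 0.74 ± 0.17 (SE), in a test also chosen after the results, which argues against such a loss as the whole cause of the lower family genes.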
